A study of Mus musculus with 34 samples.

How the data were processed

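The cortex libraries were made by the submitters from TRIzol-extracted RNA with a poly-A mRNA kit and read as paired 150-base ends. The counts of the deposited table were whole numbers per gene and mouse, which the authors made with bcl2fastq, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.5 and HTSeq 0.6.1 on mouse build GRCm38. The labels list these tools without their roles and do not state the strand setting of the counting. The RPKM values of the deposited table were scaled by the authors per kilobase of gene length and by the total of each count column. This was checked: RPKM recomputed from the counts differed by at most 9.07e-15 in relative size over 713471 nonzero values, so the counts were used throughout and the RPKM values served for gene lengths. Gene positions came from GENCODE M21, which placed 55144 of the 55385 genes listed and left 241 without a position. The tables held 34 mice, each in a column of its own. The series description gives 6 mice for 5xFAD tofacitinib and 4 for 5xFAD-Dp16 sham, of which 5 and 3 were analysed here.

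Genes were tested with edgeR 4.0.16 in R 4.3.3. filterByExpr on the 8 groups kept 17632 genes, libraries were scaled by TMM, and a single quasi-likelihood fit held all 34 libraries with a term for each group and a term for sex. F-tests were two-sided and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The SE of a log2 fold change was its size divided by the square root of F. CPM values used TMM-scaled totals. There were 18 comparisons: genotypes within sham, genotypes within tofacitinib, tofacitinib against sham within each genotype and as their unweighted mean, the interaction of the lesions over both treatments, the interactions of drug and genotype, and the interaction of 5xFAD and sex. Comparisons that share a wild-type group are not independent, and overlaps were counted only between comparisons without shared libraries. Beside each overlap stands the number expected if the calls were independent, the product of both counts divided by the genes tested.

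A set of 31 gene lists was fixed before the data were examined. It covered microglia, interferon, JAK-STAT, complement, astrocyte, oligodendrocyte, neuron, synapse, immediate early, glucocorticoid, circadian, stress response, cholesterol, oxidative phosphorylation, mitochondrial, ribosomal, vascular, choroid plexus, blood, lymphocyte, peripheral myeloid, striatum, hippocampus and thalamus genes, and the duplicated segment. Genes of the segment were left out of the other lists. The segment was taken as chromosome 16 from 75540514 to 97962622, with 384 genes listed and 106 tested. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, two-sided. The same test with an estimated correlation, and fry, were run beside it. The PValue of fry asks whether the genes of a list move on balance in 1 direction and its Mixed value asks for change in either direction, and neither compares the list with other genes. A count adjusted over the list alone used the p values of the list's members only.

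Segment dosage was the median over segment genes of log2 CPM relative to the wild-type sham mean, compared between carriers and non-carriers with a two-sided exact permutation test. Genes were named by a rule fixed before the data were examined. It took the 8 largest changes in each direction among called genes with a mean of at least 1 CPM and complete separation of the libraries, up to 4 members of each called list with its usual markers, and a fixed panel of transgene, microglial, interferon, receptor and Janus kinase genes, some of which are not reported here. Genes outside the rule were said to be chosen after their values were seen. Genes with counts of 0 in every library of a group were given without a fold change.

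Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom with sample weights, no low-count filter, a mean of at least 1 CPM, a fold change minimum of 1.2, DESeq2 size factors, scaling without segment genes, 2 surrogate variables from sva 3.50.0, no sex term, replicate number as a block, a fit of only the groups compared, and each library left out in turn. After the data were seen 3 more were added: leaving out wild-type sham 2 and 5xFAD tofacitinib 2 together, removing a per-library loess trend on gene length, and contrasts of carriers against non-carriers averaged over the other factors. Sex labels were checked against sex-linked genes and fitted in 34 of 34 libraries.

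The fit was tested on simulated data with negative binomial counts of the same size and spread, in which 200 genes were changed. For Dp16 against wild-type sham it recovered 21 of 67 genes changed 1.5-fold and 44 of 66 changed 2-fold. Over 12 comparisons the share of false calls lay between 1.22% and 8.65%, and a type I interferon list raised 1.5-fold was called in each while at most 1 of the 30 other lists was called. The simulated genes were drawn independently, without correlation between genes or differences in tissue sampled between mice. These shares therefore need not hold for the real libraries, least of all for the list tests.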

Results

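Poly-A RNA was sequenced from the cortex of 34 mice aged 6 months, 16 of them female and 18 male. The mice were wild-type, Dp16, 5xFAD or 5xFAD-Dp16. Dp16 mice carry a duplicated segment of mouse chromosome 16 that corresponds to much of the human chromosome that is trisomic in Down syndrome. 5xFAD mice carry human transgenes with familial Alzheimer's disease mutations, driven by Thy1 sequences, and develop amyloid plaques. Each genotype received tofacitinib, an inhibitor of the Janus kinases that signal below interferon and other cytokine receptors, at 15 mg/kg by daily oral gavage for 1 month, or a sham gavage of 0.5% methylcellulose. The wild-type groups had 5 sham and 5 tofacitinib mice, Dp16 had 3 and 5, 5xFAD had 4 and 5, and 5xFAD-Dp16 had 3 and 4. In the same order, females numbered 2 and 2, 2 and 3, 1 and 2, and 2 and 2. Each library came from 1 mouse and held between 16029841 and 21388650 counted reads. Of 55385 genes listed, 17632 had enough counts to be tested. On the first 2 principal components, which held 13.8% and 7.29% of the variance, wild-type sham 2 and 5xFAD tofacitinib 2 stood apart from the other libraries. The labels gave no sequencing batch or date.

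The transgene and the duplication were read in every mouse that was labelled with them. Thy1 (ENSMUSG00000032011.5, chromosome 9, 44043384 to 44048579, GRCm38), a neuronal surface glycoprotein whose sequences drive the 5xFAD transgenes, lay between 1427 and 2572 CPM (counts scaled to library size) in the 16 mice with 5xFAD. It lay between 824 and 952 CPM in the 18 mice without it. Across the 105 tested genes of the duplicated segment other than App, each library's median ratio to the wild-type sham mean was 1.45 ± 0.0449 in Dp16 sham (SD, n = 3) and 0.986 ± 0.0456 in wild-type sham (SD, n = 5). Under tofacitinib it was 1.45 ± 0.0435 in Dp16 (SD, n = 5) and 0.995 ± 0.0483 in wild-type (SD, n = 5). Duplication carriers exceeded non-carriers by 0.59 on the log2 scale among sham mice (6 against 9, two-sided exact permutation p = 0.0002, the smallest that 5005 arrangements can give). Among tofacitinib mice the difference was 0.54 (9 against 10, permutation p = 1.08e-05, the smallest that 92378 arrangements can give).

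**Figure D1:**
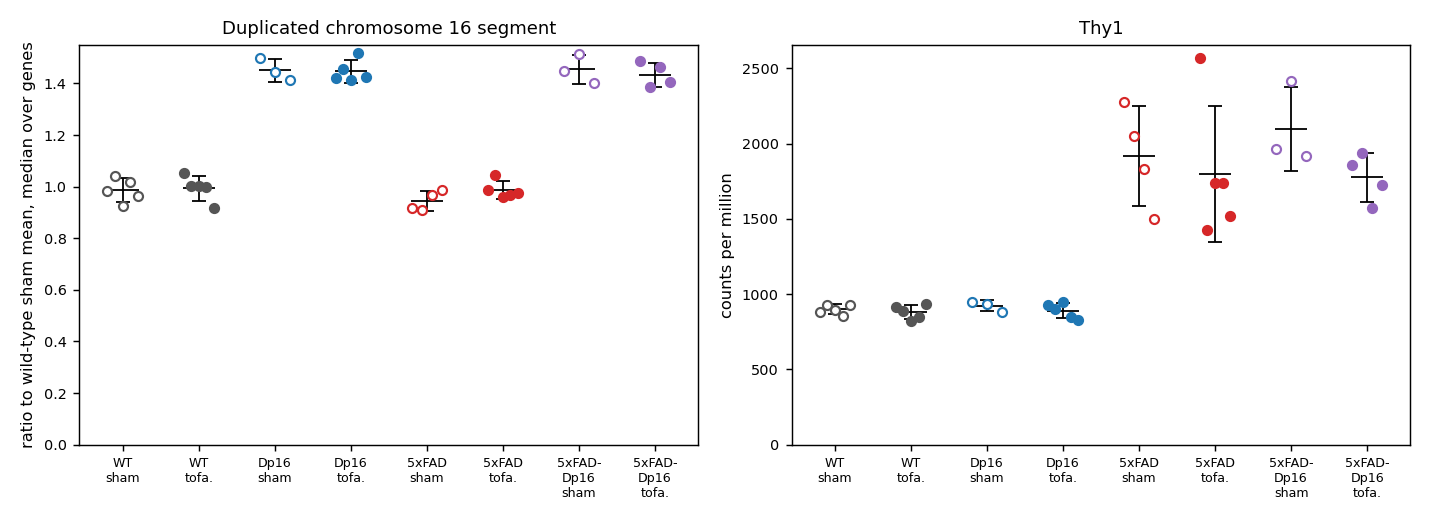
Left, ratio of segment gene levels to the wild-type sham mean (median over segment genes) for each library; right, Thy1 level in CPM for each library. Open points are sham, filled points tofacitinib and black bars mean ± SD; segment ratios lie near 1.45 in both duplication genotypes, and Thy1 lies above 1427 CPM in every mouse with 5xFAD.

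Dp16 was compared with wild-type among sham mice to find what the duplication changed by itself. Genes inside the segment dominated: 37 genes passed the threshold, 34 higher and 3 lower, and 26 of the higher genes lay in the segment. Of the 105 segment genes other than App, 97 were higher, with a median 1.45-fold. The receptors of interferon were among them. Ifnar1 (ENSMUSG00000022967.13, chromosome 16, 91485238 to 91507441) and Ifnar2 (ENSMUSG00000022971.18, 91372783 to 91405589), the chains of the type I interferon receptor, rose 1.76-fold and 1.80-fold. Ifnar1 went from 31.7 ± 2.29 CPM (SD, n = 5) to 55.8 ± 2.61 (SD, n = 3), with an edgeR adjusted p of 1.94e-06. Ifngr2 (ENSMUSG00000022965.8, 91547072 to 91565623), a chain of the interferon gamma receptor, rose 1.75-fold, from 49.2 ± 3.98 CPM to 86.5 ± 4.37.

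Other segment genes rose by similar amounts. Dyrk1a (ENSMUSG00000022897.15, 94570010 to 94695517), a kinase studied for its dosage in Down syndrome, rose 1.47-fold (adjusted p = 0.00474), from 76.0 ± 4.95 CPM to 111 ± 2.64. Rcan1, an inhibitor of calcineurin, rose 1.46-fold, and Brwd1, a bromodomain protein, 1.64-fold (adjusted p = 6.35e-07). The largest changes in the segment by the naming rule were in Donson, a replication fork protein (2.26-fold), C2cd2 (2.17-fold), Rbm11, an RNA-binding splicing regulator (2.15-fold), and Vps26c, a subunit of an endosomal recycling complex (1.89-fold). App (ENSMUSG00000022892.11, 84949685 to 85173766), the amyloid precursor protein gene, was at 2297 ± 245 CPM against 1547 ± 138 and missed the threshold (log2 difference 0.56, adjusted p = 0.0703). Sod1 (log2 difference 0.46, adjusted p = 0.186) and Il10rb, an interleukin receptor chain (0.23, adjusted p = 0.883), missed it as well. Counted over the segment list alone, 61 of its 106 tested genes passed (adjusted over the list alone), and the segment list was called with the preset and with the estimated correlation (adjusted p = 3.92e-17 with an estimated correlation).

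**Figure D2:**
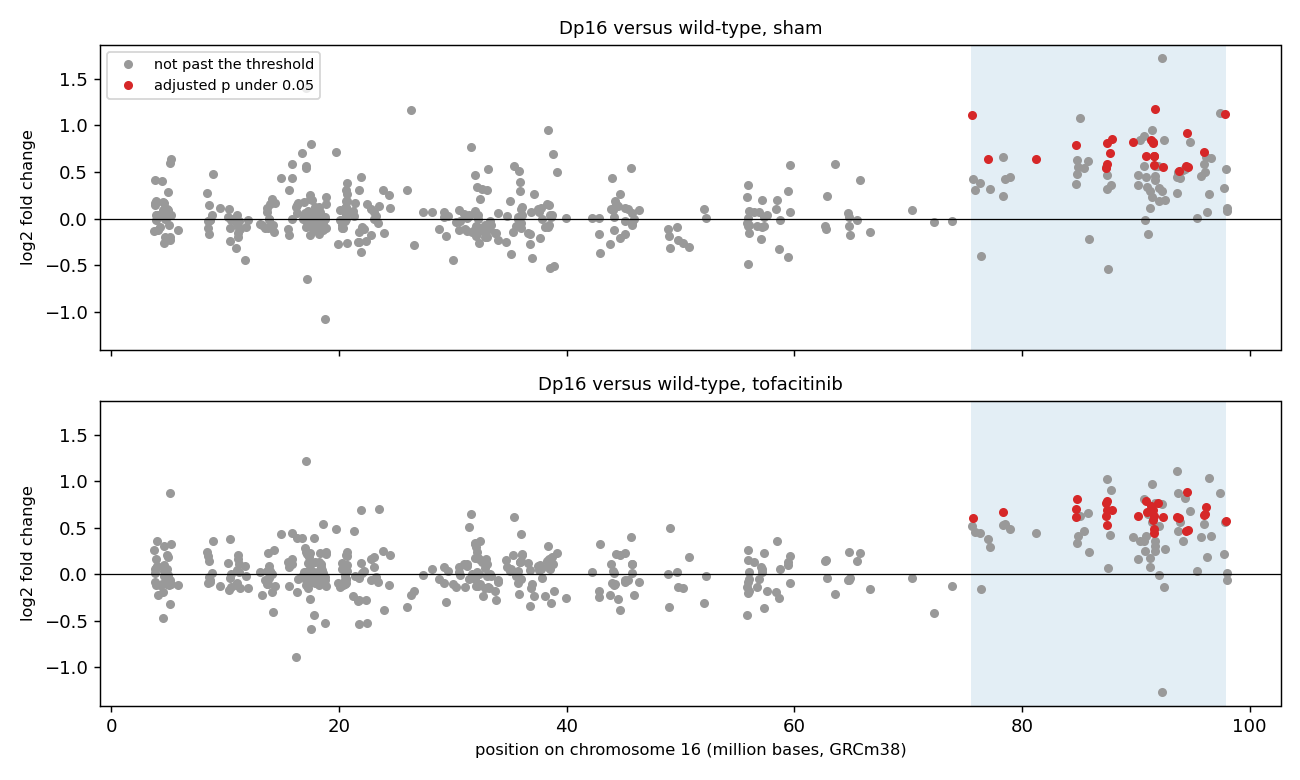
Log2 fold change of Dp16 against wild-type along chromosome 16 (position in bases, GRCm38), sham at the top and tofacitinib at the bottom, for genes with a mean of at least 1 CPM. Red points had an adjusted p under 0.05 and the shaded stretch is the duplicated segment, where 26 sham and 31 tofacitinib genes passed the threshold.

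Outside the segment 11 genes passed, 8 higher and 3 lower. Slc25a34, a mitochondrial carrier, rose 1.80-fold, from 8.55 ± 1.85 CPM to 15.5 ± 2.29. The predicted gene Gm49980 (ENSMUSG00000117465.1, chromosome 18, 30267249 to 30272133) fell by 1.69 on the log2 scale, from 5.82 ± 1.55 CPM to 1.84 ± 0.721. Others were chosen after their values were seen. They include Slc5a5, the sodium iodide symporter (1.61-fold), Cort, the neuropeptide cortistatin (8.26 ± 2.40 CPM to 16.9 ± 4.39), and the agouti gene, symbol a (ENSMUSG00000027596.10, chromosome 2, 154791402 to 155051012). The agouti gene was listed at 0 in all 5 wild-type sham libraries and at 1.78 ± 0.274 CPM in Dp16 sham (SD, n = 3).

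Gene lists fixed in advance were compared as well. The type I interferon response list, from which the segment genes Mx1 and Mx2 were left out, was higher with 29 of its 36 measured members above 0 and a median log2 difference of 0.28 (camera adjusted p = 5.25e-05; adjusted p = 0.589 with an estimated correlation). Irf7, a transcription factor of the interferon response, had a log2 difference of 0.94 and Bst2, an antiviral membrane protein, 0.78, and neither gene passed. The interferon gamma and antigen presentation list was higher with 30 of 34 members above 0 (median 0.22, adjusted p = 5.25e-05; adjusted p = 0.292 with an estimated correlation), and 1 member passed when adjusted over the list alone. Its largest differences were in major histocompatibility genes: H2-Ab1 at 4.20 ± 0.124 CPM against 1.55 ± 0.707 (adjusted p = 0.214) and H2-D1 at 57.9 ± 8.78 against 42.0 ± 5.39 (adjusted p = 0.439). All 13 protein-coding transcripts of the mitochondrial genome were lower (median -0.34, adjusted p = 2.19e-10; adjusted p = 0.292 with an estimated correlation), and 7 passed when adjusted over the list alone. The myelinating oligodendrocyte list was lower, with 2 of 17 members above 0 (adjusted p = 0.000764; adjusted p = 0.726 with an estimated correlation). Markers of the striatum, a neighbour of the cortex, were also lower (median -0.83, adjusted p = 4.55e-06; adjusted p = 0.621 with an estimated correlation) and markers of the hippocampus higher (median 0.54, adjusted p = 0.0227; adjusted p = 0.726 with an estimated correlation). Without Dp16 sham 2 the number of genes past the threshold was 18.

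5xFAD was compared with wild-type among sham mice for the effect of the transgenes. Only Thy1 passed, at 1918 ± 331 CPM (SD, n = 4) against 901 ± 31.7 (SD, n = 5), 2.15-fold (edgeR adjusted p = 1.86e-07). Genes of plaque-associated microglia were among many that lay just short of the threshold. Cst7 (ENSMUSG00000068129.5, chromosome 2, 150570415 to 150578944), a protease inhibitor induced in these cells, was at 6.25 ± 5.18 CPM against 0.0989 ± 0.113. Clec7a (ENSMUSG00000079293.11, chromosome 6, 129461591 to 129472779), a pattern recognition receptor, was at 3.38 ± 2.58 CPM against 0.560 ± 0.381. Both had an adjusted p of 0.0633, as did the microglial growth factor receptor Csf1r (log2 difference 0.55) and the lysosomal marker Cd68 (0.70). Many other genes shared this value, among them the ribosomal protein gene Rpl5, so it does not set the microglial genes apart. The interferon-induced Oasl2 had a log2 difference of 1.69 (adjusted p = 0.0566). App differed by 0.25 (adjusted p = 0.201).

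By list, the disease-associated microglia genes were higher in 5xFAD sham, 16 of 24 above 0 with a median of 0.24 (adjusted p = 0.00503; adjusted p = 0.680 with an estimated correlation), and 7 passed when adjusted over the list alone. The homeostatic microglia list was higher too, 13 of 15 (adjusted p = 0.00192; adjusted p = 0.680 with an estimated correlation; 5 adjusted over the list alone), as was the type I interferon list (adjusted p = 0.0190; adjusted p = 0.680 with an estimated correlation; 2 adjusted over the list alone). The strongest list results went the other way. Of 70 nuclear genes of oxidative phosphorylation, 67 were lower, with a median of -0.56 (adjusted p = 4.28e-24; adjusted p = 0.680 with an estimated correlation). Ndufb9, a subunit of complex I, was at 228 ± 15.4 CPM against 408 ± 108 (adjusted p = 0.0633), and Uqcrb, of complex III, at 87.0 ± 12.7 against 142 ± 31.3. All 38 cytosolic ribosomal protein genes were lower, with a median of -0.60 (adjusted p = 8.30e-19; adjusted p = 0.680 with an estimated correlation), among them Rpl5 at 344 ± 43.8 CPM against 666 ± 223. When adjusted over the list alone, 55 oxidative phosphorylation genes were lower and 1 higher, and 37 ribosomal genes were lower. Change across genes followed transcript length (Spearman's rho 0.40 over all tested genes, which are not independent replicates), and these lists hold short transcripts. The call count was unstable: 4357 genes had an unadjusted p under 0.05, DESeq2 called 1587 genes and limma-voom 2516, and 2008 genes passed in edgeR without wild-type sham 3.

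5xFAD-Dp16 was compared with wild-type among sham mice for both lesions together. The 64 genes past the threshold, 55 higher and 9 lower, comprised 33 segment genes and 31 others. Among the others were microglial, interferon and antigen presentation genes. Cst7 rose to 5.72 ± 4.75 CPM (SD, n = 3) from 0.0989 ± 0.113 (SD, n = 5; edgeR adjusted p = 0.0258). Lgals3bp (ENSMUSG00000033880.11, chromosome 11, 118392751 to 118402092), a secreted galectin-binding protein induced by interferon, rose 2.67-fold (adjusted p = 0.00132), and Oasl2 3.03-fold (adjusted p = 0.0177). B2m (ENSMUSG00000060802.8, chromosome 2, 122147686 to 122153083), the light chain of class I histocompatibility molecules, rose 1.44-fold, from 116 ± 8.78 CPM to 174 ± 37.6 (adjusted p = 0.00567). H2-D1 (ENSMUSG00000073411.12, chromosome 17, 35262730 to 35267499), a class I heavy chain, rose 1.61-fold (adjusted p = 0.0131), and H2-K1, another, had a log2 difference of 0.65 (adjusted p = 0.0574). Vwf, von Willebrand factor of endothelial cells, rose 2.09-fold, Tep1, a telomerase-associated protein, 2.79-fold, and Slc7a3, a cationic amino acid transporter, 2.15-fold.

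In the segment Ifnar1 rose 1.95-fold (adjusted p = 6.17e-08), Ifnar2 1.71-fold, Ifngr2 1.61-fold, Dyrk1a 1.60-fold, the kinase Hunk 2.72-fold and the potassium channel Kcnj6 2.50-fold. App passed here, at 2582 ± 191 CPM against 1547 ± 138 (1.65-fold, adjusted p = 0.00243), and Thy1 rose 2.26-fold. Genes that fell included Crem, a cAMP-responsive transcription factor (fell by 0.97 on the log2 scale), the chromatin proteins Hmgb3 (fell by 0.72), Hmgb1 (fell by 0.44) and Ptma (fell by 0.50), the RNA export factor Alyref (fell by 0.53), the transcriptional regulator Ifrd1 (fell by 0.61) and Timm44, of mitochondrial protein import (fell by 0.45).

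The type I interferon list had 34 of 36 members above 0, with a median of 0.55 (adjusted p = 1.07e-10; adjusted p = 0.169 with an estimated correlation), 2 were called over all genes and 12 passed when adjusted over the list alone. The interferon gamma and antigen presentation list had 27 of 34 members above 0 (median 0.33, adjusted p = 2.08e-05; adjusted p = 0.253 with an estimated correlation), with 2 called and 3 adjusted over the list alone. The disease-associated microglia list had 20 of 24 above 0 (adjusted p = 0.00336; adjusted p = 0.536 with an estimated correlation), and complement genes were higher (adjusted p = 0.0225; adjusted p = 0.471 with an estimated correlation). Oxidative phosphorylation (median -0.40) and ribosomal protein genes (median -0.53) were again lower, with adjusted p of 1.50e-17 and 1.72e-16, and striatal markers lay lower (median -1.21, adjusted p = 7.80e-08; adjusted p = 0.471 with an estimated correlation). With an estimated correlation both of the former had an adjusted p of 0.536. Without 5xFAD-Dp16 sham 2 the number of genes past the threshold was 23.

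5xFAD-Dp16 was compared with 5xFAD among sham mice for what the duplication added to the amyloid model. All 18 genes past the threshold were higher and 16 lay in the segment. Brwd1 rose 1.62-fold (edgeR adjusted p = 4.30e-06), Ifngr2 1.65-fold (adjusted p = 9.16e-05), Ifnar1 1.58-fold (adjusted p = 0.00026) and Cxadr, a cell adhesion receptor, 1.73-fold. Slc5a5 rose 1.73-fold outside the segment, to 34.1 ± 1.28 CPM (SD, n = 3), and the agouti gene, again chosen after its values were seen, was listed at 0 in all 4 5xFAD sham libraries and at 1.08 ± 0.250 CPM in 5xFAD-Dp16. The type I interferon list was higher, 32 of 36 above 0 with a median of 0.32 (adjusted p = 6.15e-06; adjusted p = 0.282 with an estimated correlation), as was the interferon gamma list, 26 of 34 (adjusted p = 0.000362; adjusted p = 0.282 with an estimated correlation). Of the mice compared, 2 of 3 with 5xFAD-Dp16 and 1 of 4 with 5xFAD were female, and the sex term was shared by all groups. Among mice with 5xFAD the type I interferon score was higher in females, so sex may account for a part of that list's difference. B2m was at 174 ± 37.6 CPM against 131 ± 12.2 and was not called (adjusted p = 0.671). Homeostatic microglia genes were lower (adjusted p = 0.0012), as were circadian clock genes (adjusted p = 9.73e-05) and striatal markers (median -1.16, adjusted p = 3.24e-12), each with adjusted p = 0.282 with an estimated correlation. The segment list held with an estimated correlation (adjusted p = 6.70e-19), and 63 of its genes passed when adjusted over the list alone. Without 5xFAD-Dp16 sham 4 the number of genes past the threshold was 11.

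5xFAD-Dp16 was compared with Dp16 among sham mice for what the transgenes added to the duplication. Thy1 passed, at 2100 ± 278 CPM against 924 ± 35.0 (SD, n = 3 each), 2.27-fold, with an edgeR adjusted p of 6.26e-06. Cst7 was at 5.72 ± 4.75 CPM against 0.113 ± 0.148 (adjusted p = 0.703). Disease-associated microglia genes were higher in 17 of 24 (adjusted p = 0.00253), type I interferon genes in 29 of 36 (adjusted p = 0.00253) and homeostatic microglia genes as a list (adjusted p = 0.00103). Oxidative phosphorylation (median -0.33, adjusted p = 7.39e-14) and ribosomal protein genes (median -0.36, adjusted p = 9.69e-10) were lower. The adjusted p of these lists with an estimated correlation lay between 0.671 and 0.804.

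Whether the lesions combined other than additively on the log scale was asked with an interaction over both treatments. The gene mt-Atp6 (ENSMUSG00000064357.1, mitochondrial genome, 7927 to 8607), a subunit of ATP synthase, passed, with a log2 difference of 0.62 (SE 0.105, adjusted p = 0.0203). Its level was lower in each single lesion than in wild-type sham mice, at 134 ± 11.8 CPM in wild-type, 104 in 5xFAD and 96.4 ± 12.4 in Dp16, while 5xFAD-Dp16 lay at 111 ± 12.2. The whole mitochondrial list went the same way: all 13 transcripts were above 0, with a median of 0.42 (adjusted p = 5.89e-29), and 12 passed when adjusted over the list alone. This call held with an estimated correlation (adjusted p = 0.0102). The gene was no longer called in 10 of the 34 fits that left out 1 library.

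Genotypes were compared again among tofacitinib mice, in libraries not shared with the sham comparisons. In Dp16 against wild-type 45 genes passed, 38 higher and 7 lower, and 31 lay in the segment. Sham and tofacitinib calls shared 19 higher genes, where 0.0733 would be shared if calls were independent, and among the shared genes 2 lay outside the segment, the agouti gene and Cort. Cort rose 2.05-fold here, from 7.79 ± 0.395 CPM to 15.5 ± 2.62 (SD, n = 5 each, edgeR adjusted p = 0.00687). Gm49980 was lower in both. Ifnar1 rose from 37.3 ± 2.61 CPM to 55.9 ± 6.46, Ifnar2 1.66-fold, Ifngr2 1.62-fold, Dyrk1a 1.39-fold and Sod1, superoxide dismutase, 1.55-fold (adjusted p = 0.00207). Outside the segment Selenov, a selenoprotein, rose 4.97-fold, Lin28b, a regulator of let-7 microRNAs, 2.82-fold, and Ggcx, which carboxylates vitamin K-dependent proteins, 1.66-fold. Alpl, alkaline phosphatase (fell by 0.82 on the log2 scale), Mfge8, an opsonin made by astrocytes (fell by 0.55), and Fam50a (fell by 0.40) were lower. Cbs, cystathionine beta-synthase, chosen after its values were seen, fell by 0.74.

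In the same comparison the type I interferon list had 29 of 36 members above 0 (adjusted p = 0.0110) and the interferon gamma list 22 of 34 (adjusted p = 0.0163), each with adjusted p = 0.724 with an estimated correlation. Homeostatic microglia genes were lower (adjusted p = 0.00041; adjusted p = 0.344 with an estimated correlation), with 4 adjusted over the list alone. Oxidative phosphorylation genes were higher (adjusted p = 8.51e-06), with adjusted p = 0.724 with an estimated correlation. Lymphocyte genes, of which 4 were measured, were higher (adjusted p = 0.0125; adjusted p = 0.193 with an estimated correlation), and so were blood markers (adjusted p = 0.0115; adjusted p = 0.724 with an estimated correlation). Without wild-type tofacitinib 1 the number of genes past the threshold was 97.

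In 5xFAD against wild-type under tofacitinib 2 genes passed. Clec7a rose by 4.00 on the log2 scale, from 0.324 ± 0.173 CPM to 5.61 ± 5.22 (SD, n = 5 each, edgeR adjusted p = 0.0133), and Thy1 rose 2.03-fold. Cst7 was at 6.87 ± 5.18 CPM against 0.0578 ± 0.0807 (adjusted p = 0.0665), and Ccl6, a microglial chemokine, had a log2 difference of 1.82 (adjusted p = 0.102). The disease-associated microglia list was higher, 22 of 24 above 0 with a median of 0.47 (adjusted p = 1.37e-20), 1 called and 12 adjusted over the list alone. This list held with an estimated correlation (adjusted p = 0.0231). Type I interferon genes were higher in 29 of 36 (median 0.33, adjusted p = 1.63e-06; adjusted p = 0.274 with an estimated correlation). Complement (adjusted p = 0.00247; adjusted p = 0.180 with an estimated correlation) and cholesterol synthesis genes (adjusted p = 9.22e-07; adjusted p = 0.143 with an estimated correlation; 3 adjusted over the list alone) were higher. All 13 mitochondrial transcripts were lower (median -0.32, adjusted p = 3.01e-16; adjusted p = 0.0782 with an estimated correlation), and 10 passed when adjusted over the list alone. Synapse genes were lower (adjusted p = 1.13e-08; adjusted p = 0.395 with an estimated correlation), in a group where the thalamus score of 5xFAD tofacitinib 2 was 5.53 and that of the other libraries at most 4.16. Without 5xFAD tofacitinib 1 the number of genes past the threshold was 9, and without wild-type tofacitinib 1 it was 1.

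In 5xFAD-Dp16 against wild-type under tofacitinib 54 genes passed, 38 higher and 16 lower, of which 26 lay in the segment. Microglial genes rose: Cst7 to 5.21 ± 3.68 CPM from 0.0578 ± 0.0807 (n = 4 and 5, edgeR adjusted p = 0.0242), Clec7a 15.5-fold (adjusted p = 0.0037), Cd52, a leukocyte surface glycoprotein, 3.24-fold (adjusted p = 0.006) and Lyz2, lysozyme, 2.34-fold (adjusted p = 0.0426). The interferon-induced Ifi27 rose 1.63-fold (adjusted p = 0.011) and H2-D1 1.48-fold (adjusted p = 0.0453). Irf7 had a log2 difference of 1.14 (adjusted p = 0.0528). Among the lower genes were Upf3b, of nonsense-mediated decay (fell by 0.58 on the log2 scale), the histone chaperone Anp32b (fell by 0.50), Hmgb1 (fell by 0.41) and Fam50a (fell by 0.50). Sham and tofacitinib calls shared 25 higher genes against 0.119 if independent, of which the 5 outside the segment were the agouti gene, Cst7, H2-D1, Slc5a5 and Thy1. They shared 3 lower genes, Gm49980, Hmgb1 and Ptma, against 0.00817.

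Of 36 type I interferon genes 35 were above 0, with a median of 0.77 (adjusted p = 2.64e-27), 1 called and 17 adjusted over the list alone, and of 34 interferon gamma and antigen presentation genes 30 were above 0 (median 0.41, adjusted p = 2.79e-11), 1 called and 6 adjusted over the list alone. Both held with an estimated correlation (adjusted p = 0.00215 and 0.0118). The mouse 5xFAD-Dp16 tofacitinib 1 had a type I interferon score (mean log2 CPM) of 2.92 against 2.06 to 2.21 in the others of its group, and without it the list had a median of 0.61 and stayed past the threshold. Disease-associated microglia genes were higher in 19 of 24, 4 of them called, and 6 higher and 1 lower passed when adjusted over the list alone (adjusted p = 3.37e-10; adjusted p = 0.0840 with an estimated correlation). Cholesterol synthesis genes were higher in 21 of 23 (adjusted p = 1.93e-07; adjusted p = 0.0840 with an estimated correlation), with Msmo1, a sterol oxidase, at a log2 difference of 0.44 (adjusted p = 0.0528). Reactive astrocyte genes were higher (adjusted p = 0.0322; adjusted p = 0.465 with an estimated correlation). Myelinating oligodendrocyte genes were lower, with 1 of 17 above 0 (adjusted p = 1.24e-08; adjusted p = 0.355 with an estimated correlation; 6 adjusted over the list alone). Without 5xFAD-Dp16 tofacitinib 2 the number of genes past the threshold was 22.

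**Figure D3:**
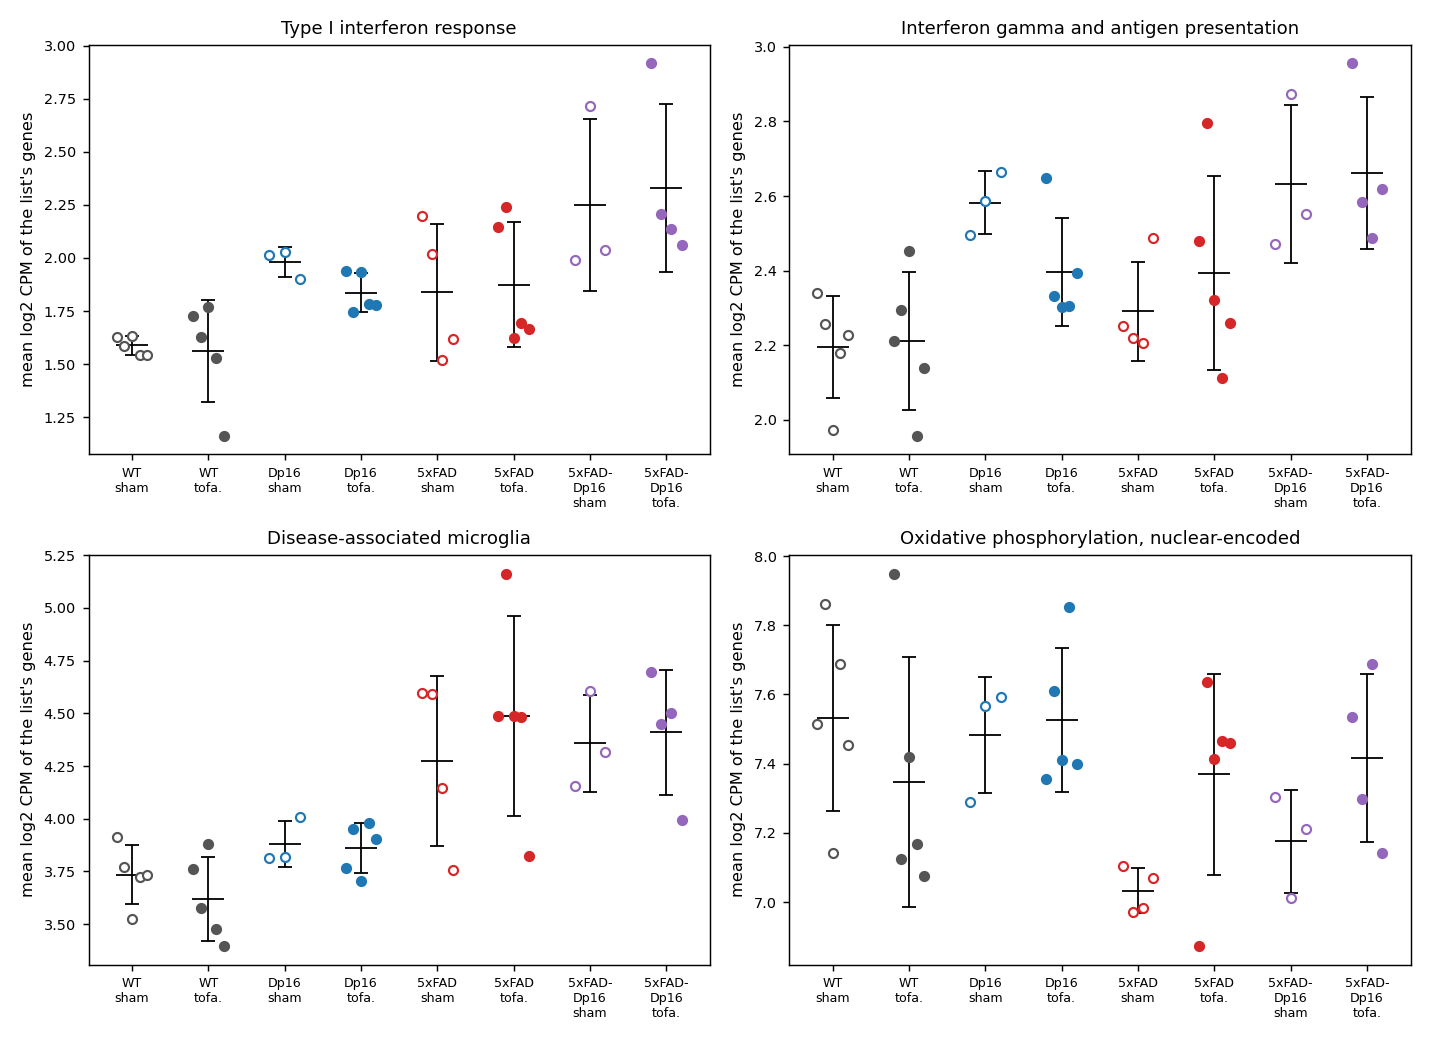
Mean log2 CPM over the members of 4 gene lists in each library, by genotype and treatment, with black bars for mean ± SD. The type I interferon and antigen presentation scores have their highest means in 5xFAD-Dp16 mice, and the disease-associated microglia score is higher with than without 5xFAD in both treatments.

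The drug comparison asked whether tofacitinib changed gene expression in each genotype. At an adjusted p under 0.05 edgeR called 0 genes in wild-type, Dp16, 5xFAD and 5xFAD-Dp16 mice and 0 in the mean over the 4 genotypes. The counts at an unadjusted p under 0.05 were 1276, 357, 2592, 322 and 585, where 882 would arise by chance. DESeq2 called 2, 1, 0, 0 and 1 genes, and limma-voom called 0 except for 879 in 5xFAD. Socs3 and Cish, targets of Janus kinase signalling, were not called. Their mean levels were 2.52 and 7.18 CPM, where a modest change could be missed. Over the 4 genotypes the log2 difference was 0.15 for Socs3, a feedback inhibitor of cytokine signalling (SE 0.152), and 0.05 for Cish, another (SE 0.0928). The type I interferon list had 17 of 36 members above 0 (median -0.01, adjusted p = 0.814). The interferon gamma list had a median of -0.01 (adjusted p = 0.815) and the JAK-STAT list had 16 of 32 above 0, with a median of 0.00, a mean of -0.02 and a camera direction down (adjusted p = 0.605). On simulated data the mean over genotypes recovered 35 of 67 genes given the smallest change, whose median fitted fold was 1.26, and 56 of 67 changed 1.5-fold. Those genes were drawn independently, so fewer may be recovered in the real libraries. Within Dp16 mice the antigen presentation list was lower with tofacitinib in 23 of 34 members (adjusted p = 0.0481; adjusted p = 0.854 with an estimated correlation), among them Cd74, the class II invariant chain (log2 difference -0.57, adjusted p = 1). Lists with no call in the mean over genotypes included the disease-associated microglia (18 of 24 above 0, median 0.05), complement (adjusted p = 0.827), reactive astrocyte (adjusted p = 0.576), inhibitory neuron (adjusted p = 0.646), integrated stress response (adjusted p = 0.815), endothelial (adjusted p = 0.590), blood (adjusted p = 0.571), lymphocyte (adjusted p = 0.859) and thalamus (adjusted p = 0.0776) lists.

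Gene lists were also compared between tofacitinib and sham within each genotype. Oxidative phosphorylation genes were higher with tofacitinib in 67 of 70 members in 5xFAD (median 0.39, adjusted p = 1.37e-17) and in 5xFAD-Dp16 (median 0.25, adjusted p = 2.64e-13), and lower in wild-type (median -0.18, adjusted p = 3.30e-08). Ribosomal protein genes moved alike, with medians of 0.42, 0.38 and -0.17 (adjusted p = 2.31e-11, 3.74e-17 and 4.61e-06). With an estimated correlation the adjusted p was 0.685 in 5xFAD, 0.892 in 5xFAD-Dp16 and 0.878 in wild-type. A test of list scores with the mouse as the unit was chosen after the results were seen. For both lists its exact permutation adjusted p was 0.633 in 5xFAD, 0.949 in 5xFAD-Dp16 and 0.810 in wild-type. The 5xFAD sham mice are those in which both lists lay below wild-type sham, so these results are not independent. With 2 surrogate variables in the model the wild-type medians were 0.06 and 0.08. Synapse genes were lower in all 28 members in 5xFAD (adjusted p = 2.04e-10; adjusted p = 0.685 with an estimated correlation), such as Cplx2, of vesicle release, at 1621 ± 311 CPM against 2072 ± 64.1. The mouse 5xFAD tofacitinib 2 had a synapse score of 8.05 against 8.78 to 9.07 in the others of its group, with thalamus markers at 5.53 (3.77 to 4.16) and myelinating oligodendrocyte genes at 8.37 (7.36 to 7.64). Without it the median of the synapse list moved from -0.27 to -0.14, still past the threshold. Myelinating oligodendrocyte genes were higher in Dp16 and 5xFAD (adjusted p = 0.00360 and 0.00201), choroid plexus genes were lower in Dp16 and higher in 5xFAD (adjusted p = 0.00360 and 0.00120), and none of these calls held with an estimated correlation. The mean oligodendrocyte score of 5xFAD sham mice was 7.47, inside the range of the 5xFAD tofacitinib mice other than 5xFAD tofacitinib 2. The choroid plexus calls depended on single libraries: that in Dp16 was lost without Dp16 sham 1 or Dp16 tofacitinib 3, and that in 5xFAD without 5xFAD tofacitinib 2. Homeostatic astrocyte genes were higher in all 15 members in wild-type (adjusted p = 2.77e-05; adjusted p = 0.878 with an estimated correlation), such as Fgfr3 (log2 difference 0.33, adjusted p = 0.599). Over the 4 genotypes immediate early genes were lower and glucocorticoid response genes higher (adjusted p = 0.0194 and 0.0392, each with adjusted p = 0.769 with an estimated correlation), and so were mural cell and fibroblast genes (adjusted p = 0.0392; adjusted p = 0.769 with an estimated correlation). The immediate early score of 5xFAD tofacitinib 2 was 4.14 against 5.50 to 5.66 in the others of its group. The 5xFAD sham mean was 5.55, so the lower immediate early score within 5xFAD rested on this library. The number of genes called in 5xFAD was 411 without 5xFAD tofacitinib 1.

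Whether the drug effect differed from that in wild-type was tested with an interaction for each other genotype. edgeR called 0 genes for Dp16, 5xFAD and 5xFAD-Dp16, with 678, 3562 and 1175 genes at an unadjusted p under 0.05. DESeq2 called 3, 1 and 0, and limma-voom 0, 3500 and 0. No interferon or JAK-STAT list was called in these interactions. In the 5xFAD interaction oxidative phosphorylation genes had a median of 0.59 (adjusted p = 1.18e-18) and ribosomal protein genes of 0.61 (adjusted p = 2.12e-12), each with adjusted p = 0.721 with an estimated correlation. The count in the 5xFAD interaction was 2343 without wild-type tofacitinib 1 and 1511 without 5xFAD tofacitinib 1.

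The effect of 5xFAD was also compared between the sexes. edgeR, DESeq2 and limma-voom each called 0 genes, and 552 had an unadjusted p under 0.05 in edgeR. Lists were called all the same, 17 of the 31, and none held with an estimated correlation, so the calls were not confined to immune lists. Among them, the 5xFAD effect, male minus female, had a median of -0.42 over the type I interferon genes (adjusted p = 9.18e-10; adjusted p = 0.154 with an estimated correlation). It had a median of -0.27 over the disease-associated microglia genes (adjusted p = 1.06e-06; adjusted p = 0.160 with an estimated correlation).

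Of the list calls in all comparisons, 9 held with an estimated correlation: the segment list in its 5 comparisons, the mitochondrial genome in the interaction of the lesions, disease-associated microglia in 5xFAD under tofacitinib, and both interferon lists in 5xFAD-Dp16 under tofacitinib. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, called 14 of the pairs.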

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

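Of the tests reported here, the removal of the gene length trend, the fit with region scores, the comparison of the 5xFAD effect with that under tofacitinib, the count of agouti reads in carriers, the Thy1 check of low scoring carriers and the test of sex were chosen only after the results were seen. A simple spread test was applied to 276 combinations of group and value, each list score or reported panel gene within a group, and it picked out 18 values of libraries that lay far from the others of their group. It picks about 1 in 20 by chance, so 13.8 were expected.

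Most of them were list scores (mean log2 CPM). The library 5xFAD tofacitinib 2 accounted for 7: myelinating oligodendrocyte genes at 8.37 against 7.36 to 7.64 in the others of its group, excitatory neuron genes at 5.48 against 6.94 to 7.33, synapse genes at 8.05 against 8.78 to 9.07, immediate early genes at 4.14 against 5.50 to 5.66, hippocampus markers at 3.46 against 1.70 to 1.92, thalamus markers at 5.53 against 3.77 to 4.16, and segment genes at 3.49 against 3.31 to 3.36. Hippocampus markers stood at 4.11 in wild-type tofacitinib 3 (1.72 to 1.93 in the others), where Gfap, the intermediate filament of astrocytes, was at 387 CPM against 129 to 172. They stood at 1.70 in Dp16 tofacitinib 2 (2.09 to 2.12 in the others). Myelinating oligodendrocyte genes stood at 7.47 in wild-type sham 3 (7.66 to 7.73) and at 7.15 in 5xFAD sham 4 (7.56 to 7.58). Homeostatic microglia genes stood at 4.62 in Dp16 tofacitinib 3 (4.84 to 4.93).

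Immune scores of single mice were picked out as well. 5xFAD-Dp16 tofacitinib 1 had a type I interferon score of 2.92 (2.06 to 2.21 in the others) and the interferon-induced gene Ifit3 at 29.3 CPM (11.4 to 14.4). The antigen presentation score was 2.65 in Dp16 tofacitinib 1 (2.30 to 2.39) and 2.49 in 5xFAD sham 4 (2.20 to 2.25). Thy1 was at 2572 CPM in 5xFAD tofacitinib 1 (1427 to 1740).

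Effects that differed between groups were picked out by the interaction tests. The log2 difference of mt-Atp6 was 0.62 in the interaction of Dp16 and 5xFAD, and 7 lists were called in that interaction, of which 1 held with an estimated correlation. In the interactions of drug with Dp16, 5xFAD and 5xFAD-Dp16 the lists called numbered 7, 9 and 9, and in the interaction of 5xFAD and sex 17, none of which held with an estimated correlation.

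The lower oxidative phosphorylation and ribosomal protein genes of 5xFAD sham (median -0.58 over 108 genes) might come from gene length, since these transcripts are short (median 1005 bases against 3058.5). With a length trend removed the median was -0.23, a loss that met what was written for length before that fit was run. A set of 142 other genes as short and as abundant had a median of -0.41, so other short transcripts shared the drop. Length may account for a part. The trend was fitted with these 108 genes included, so it could also remove a drop of their own. Since both lists stayed past the threshold, it stays open whether length accounts for all. With any library left out the median was no nearer to 0 than -0.50, so a single library is argued against. With region scores as covariates it was -0.44, which argues against tissue of another region only as far as 4 marker scores capture it. Thalamus (0.19) and choroid plexus scores (-0.99) differed with 5xFAD among sham mice with sex held fixed, so the tissue sampled may account for a part. An effect of 5xFAD whatever the treatment is argued against by a median of -0.0104 under tofacitinib. An effect in sham mice alone stays open, since the medians were -0.33 and -0.36 in 5xFAD-Dp16 against Dp16 sham.

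The agouti gene was above every one of the 19 non-carriers in 15 of 15 Dp16 carriers (1.47 ± 0.438 CPM), and 16 non-carriers had counts of 0. A copied or activated stretch of chromosome 2 is argued against, since the 36 tested genes within 1 Mb had a median log2 difference of -0.00834 and 0 were called. Skin or hair on the tissue is argued against by keratin and hair genes, whose smaller exact permutation p was 0.108 with lower values in carriers. The values are consistent with reads from a construct that the Dp16 line carries, a hypothesis that genotyping of the line would test.

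The disease-associated microglia score varied among the 16 mice with 5xFAD, and 3 of them lay inside the range of mice without it: 5xFAD sham 4, 5xFAD tofacitinib 6 and 5xFAD-Dp16 tofacitinib 4. Mislabelling is argued against, since the lowest Thy1 value of these was 1503 CPM and the highest of the mice without 5xFAD 952. Tissue of another region stays open. The largest Spearman's rho was 0.26 for the thalamus score (adjusted p = 0.840 by permutation, 4 regions), which met what was written beforehand against this cause. With 16 mice such a rho cannot tell a dependence from its absence. For the same score r was 0.60, and it was 0.08 without the 2 carriers with the most extreme thalamus scores. Sex cannot be told apart from chance: females scored 0.36 higher than males as a difference of pooled means (permutation within groups, p = 0.0450), and with groups held fixed the difference was 0.38 (exact permutation p = 0.0569).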

How the results depend on the processing

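Of the settings below, the removal of the gene length trend and the joint omission of wild-type sham 2 and 5xFAD tofacitinib 2 were tests chosen only after the results were seen, and the others were set before the data were examined. The cause was not tested for results that moved.

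Counts of called genes are given where they moved by more than 1.5 times, with the counts of the edgeR fit being 37, 1 and 64 for Dp16, 5xFAD and 5xFAD-Dp16 against wild-type in sham mice, 18 for 5xFAD-Dp16 against 5xFAD, 1 for 5xFAD-Dp16 against Dp16, 1 for the interaction of the lesions, and 45, 2 and 54 for the wild-type comparisons under tofacitinib. Outside the segment the calls numbered 11 for Dp16 and 31 for 5xFAD-Dp16 in sham mice, 2 for 5xFAD-Dp16 against 5xFAD, and 14 for Dp16 and 28 for 5xFAD-Dp16 under tofacitinib. DESeq2 called 63, 1587 and 163 genes in the sham comparisons with wild-type, 38 and 2 in 5xFAD-Dp16 against 5xFAD and Dp16, and 75, 6 and 126 under tofacitinib. For the drug it called 2 in wild-type, 1 in Dp16, 1 in the mean, and 3 and 1 in the interactions with Dp16 and 5xFAD. limma-voom with sample weights called 59, 2516 and 374 in the sham comparisons with wild-type, 86 in 5xFAD-Dp16 against 5xFAD, 2 in the interaction of the lesions, and 147, 57 and 198 under tofacitinib. For the drug it called 879 in 5xFAD and 3500 in its interaction. Without a low-count filter the counts were 158, 1784 and 873, then 145, 52 and 47 for the other sham comparisons and the interaction of the lesions, and 146, 76 and 153 under tofacitinib. For the drug they were 50 in wild-type, 31 in Dp16, 642 in 5xFAD, 93 in 5xFAD-Dp16 and 51 in the mean, 79, 1166 and 272 in the interactions with genotype, and 15 for 5xFAD and sex. With 2 surrogate variables they were 71 for Dp16 in sham mice, 71 for 5xFAD-Dp16 against 5xFAD, 1 for the drug interaction with 5xFAD, and 101, 8 and 260 under tofacitinib. With a fold change minimum of 1.2 they were 10 for Dp16 and 22 for 5xFAD-Dp16 in sham mice, 8 for 5xFAD-Dp16 against 5xFAD, 0 for the interaction of the lesions, and 14 and 11 for Dp16 and 5xFAD-Dp16 under tofacitinib. A fit of only the groups compared gave 14 for Dp16 and 1500 for 5xFAD in sham mice, 41 for 5xFAD-Dp16 against 5xFAD, and 13, 0 and 5 under tofacitinib. With the gene length trend removed the counts were 232 for 5xFAD in sham mice, 39 for 5xFAD-Dp16 against 5xFAD, 0 for the interaction of the lesions and 88 for 5xFAD-Dp16 under tofacitinib. Without wild-type sham 2 and 5xFAD tofacitinib 2 they were 42 for 5xFAD-Dp16 in sham mice, 1 for the drug interaction with Dp16, and 1 and 87 for 5xFAD and 5xFAD-Dp16 under tofacitinib. List calls numbered 9 with an estimated correlation and 14 with fry, of 176.

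With each library left out in turn the counts ranged from 18 to 39 for Dp16, 1 to 2008 for 5xFAD and 23 to 82 for 5xFAD-Dp16 against wild-type in sham mice, from 11 to 16 for 5xFAD-Dp16 against 5xFAD, from 1 to 1 for 5xFAD-Dp16 against Dp16 and from 0 to 1 for the interaction of the lesions. Under tofacitinib they ranged from 32 to 97, 1 to 9 and 22 to 74. For the drug they ranged from 0 to 2 in wild-type and 0 to 411 in 5xFAD, and in the interactions from 0 to 1 for Dp16 and 0 to 2343 for 5xFAD, and they were 0 in all other fits. Segment dosage ranged from 0.57 to 0.60 in sham and from 0.53 to 0.55 in tofacitinib mice, and list calls from 135 to 174.

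Replicate numbers did not pair the mice: 98 pairs of the same number had a mean correlation of -0.04, from -0.47 to 0.24, and 0 of 34 libraries correlated best with their own number. With the number as a block the counts were 30, 1 and 49 for the sham comparisons with wild-type, 13 and 1 for 5xFAD-Dp16 against 5xFAD and Dp16, 1 for the interaction of the lesions, 30, 4 and 36 under tofacitinib, and 0 for the drug, its interactions and that of 5xFAD and sex, with 164 list calls against 159 in the 17 comparisons other than that of sex.

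Called genes kept their call in 3736 of 4817 values over all settings, lost it in 1081 and reversed direction in 0. List results kept their call in 2357 of 3184, lost it in 824 and reversed in 3, all with 2 surrogate variables: in tofacitinib against sham wild-type mice the medians were 0.0555 for oxidative phosphorylation and 0.0764 for ribosomal protein genes, and in Dp16 against wild-type under tofacitinib -0.0651 for ribosomal protein genes.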

Other observations

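In this part all tests were chosen only after the results were seen, except the comparison of random splits of the mice, which was planned for every comparison but 5xFAD-Dp16 against 5xFAD in sham mice, and the test of Thy1 level against the microglial score.

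When all 16 mice with 5xFAD were set against the 18 without it, as a contrast averaged over Dp16 status and treatment, 76 genes passed, 36 higher and 40 lower. The gene names below were chosen after their values were seen. They showed a microglial response: Cst7 (log2 difference 5.42, adjusted p = 1.79e-05), Clec7a (2.56, adjusted p = 9.67e-05), Itgax, an integrin of activated microglia (2.29, adjusted p = 0.0015), the chemokine Ccl6 (1.36, adjusted p = 0.000482), Grn, the lysosomal growth factor progranulin (0.40, adjusted p = 0.0015), Cd68 (0.56, adjusted p = 0.00528) and the lysosomal protease Ctsd (0.31, adjusted p = 0.0103). The interferon-induced Oasl2 rose by 1.07 (adjusted p = 0.000482), Lgals3bp by 0.66 and H2-D1 by 0.29. Hmgb1 fell by 0.27 and Ptn, a neurite growth factor, fell by 0.33. Of the disease-associated microglia list 8 of 24 genes were called (adjusted p = 3.49e-14; adjusted p = 0.103 with an estimated correlation), and of the type I interferon list 5 of 36 (adjusted p = 1.35e-12; adjusted p = 0.103 with an estimated correlation).

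The 15 Dp16 carriers set against the 19 non-carriers gave 374 genes, 205 higher and 169 lower, of which 70 lay in the segment and 304 outside. Among those outside, Cort rose by 0.90 (adjusted p = 1.51e-06), Slc5a5 by 0.59 and Slc25a34 by 0.71, and Cbs fell by 0.57 (adjusted p = 1.04e-05). The antigen presentation list had 6 of 34 genes called higher (median 0.20, adjusted p = 5.09e-07; adjusted p = 0.105 with an estimated correlation). Of the type I interferon genes 3 of 36 were called and 35 above 0 (median 0.29, adjusted p = 1.52e-10; adjusted p = 0.105 with an estimated correlation). Striatal markers lay lower (median -0.57, adjusted p = 7.44e-07; adjusted p = 0.492 with an estimated correlation).

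A test that takes the mouse as the unit gave related values. Among sham mice the antigen presentation score was 2.61 ± 0.147 in 6 Dp16 carriers and 2.24 ± 0.137 in 9 non-carriers (two-sided exact permutation p = 0.0004, adjusted p = 0.00619 over 31 lists), and the type I interferon score was 0.42 higher (exact permutation adjusted p = 0.0268). Females made up 4 of these carriers and 3 of the non-carriers, and with sex held fixed both differences were 0.36, of which antigen presentation passed (exact permutation adjusted p = 0.0158) and type I interferon did not (adjusted p = 0.123), so a part of the latter may come from sex. Complement (0.33), mural cell and fibroblast (0.22) and striatal markers (-1.04) passed as well (exact permutation adjusted p = 0.0443 for each), and hippocampal markers were 0.69 higher (adjusted p = 0.0527), so that the tissue sampled stays open beside an immune change. The lists adjusted together include the segment list, whose difference follows from the extra copy (exact permutation p = 0.00102). The calls at 0.0443 lay near the threshold and may depend on its place among the lists. Among tofacitinib mice the Dp16 differences were 0.21 and 0.34 and did not pass (permutation adjusted p = 0.342 and 0.330; adjusted p = 0.359 for both with sex held fixed). The disease-associated microglia score was 4.31 ± 0.317 in 7 mice with 5xFAD and 3.79 ± 0.143 in 8 without it among sham mice (exact permutation adjusted p = 0.0145; adjusted p = 0.0163 with sex held fixed). With sex held fixed homeostatic microglia (0.21), excitatory neuron (0.24), synapse (0.19), thalamus (0.19), oxidative phosphorylation (-0.41) and ribosomal protein scores (-0.49) differed as well (exact permutation adjusted p = 0.0163 for each), as did choroid plexus (-0.99), oligodendrocyte precursor (0.17) and JAK-STAT scores (0.12; adjusted p = 0.0240 for each). Among tofacitinib mice it was 4.45 ± 0.383 in 9 and 3.74 ± 0.201 in 10 (permutation adjusted p = 0.00369; adjusted p = 0.00586 with sex held fixed). For 5xFAD the type I interferon score did not pass in sham (exact permutation adjusted p = 0.193) or tofacitinib mice (permutation adjusted p = 0.0978), and with sex held fixed the adjusted p was 0.0967 and 0.0251, the latter shared by the complement score.

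The interferon score of mice with 5xFAD was 2.35 ± 0.336 in 7 females and 1.82 ± 0.239 in 9 males, and the pooled difference of 0.53 mixes sex with Dp16 status. With groups held fixed it was 0.46 (exact permutation p = 0.00556). The females include 5xFAD-Dp16 tofacitinib 1, whose score was 2.92 against 2.06 to 2.21 in the others of its group. The difference was not computed without that mouse. In mice without 5xFAD the score was 1.80 ± 0.176 in females and 1.63 ± 0.218 in males, a difference of 0.11 with groups held fixed (exact permutation p = 0.102). Whether transgene level set the microglial response could not be decided: Thy1 and the disease-associated microglia score had a Spearman's rho of 0.30 over the 16 mice (permutation p = 0.262), so a dependence and its absence cannot be told apart with these numbers. More mice of each sex per group would test both.

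The mice of the groups compared were split anew into groups of the same sizes and the fit was repeated. Chance can be excluded as the source of the number of calls for Dp16 against wild-type in sham mice (37 genes, highest other split 9), 5xFAD-Dp16 against wild-type (64, highest other 27), and 5xFAD-Dp16 against 5xFAD (18, highest other 1) in sham mice. Of these calls 26, 33 and 16 lay in the segment, whose extra copy follows the real grouping. Calls outside the segment were not counted apart in the splits, so for those calls chance is not excluded. Chance is less firmly excluded for the interaction of the lesions, with a single call (1, highest other 0, 1 of 100 splits as large), and for 5xFAD-Dp16 against wild-type under tofacitinib, where other splits called more (54, highest other 213, 4 of 100). This holds for calls alone: at an unadjusted p under 0.05 as many genes arose in 12 and 4 of 56 splits for Dp16 and 5xFAD-Dp16 against wild-type in sham mice, in 1 of 35 for 5xFAD-Dp16 against 5xFAD, and in 28 and 27 of 100 for the interaction and under tofacitinib. By that measure chance cannot be excluded for any of these 5 comparisons. For 5xFAD-Dp16 against 5xFAD the count was 659 and that of another split 642, both below the 882 expected by chance. For 5xFAD-Dp16 against Dp16 there were too few splits (1, highest other 0, 10 splits). Chance cannot be excluded for the number of calls of 5xFAD against wild-type in sham mice (1, highest other 2092, 9 of 100 as large; 2 of 100 at an unadjusted p under 0.05), nor under tofacitinib for Dp16 (45, highest other 1628, 5 of 100) and 5xFAD (2, highest other 3673, 6 of 100). Of the 45 calls for Dp16 under tofacitinib 31 lay in the segment, whose dosage differed in its own test (permutation p = 1.08e-05). Splits that called many more genes than the real grouping point to a structure of the samples other than genotype. The drug comparisons called 0 genes, so that all of 100, 56, 100, 35 and 100 splits were as large, and the highest other counts were 3198 in wild-type, 1 in Dp16, 2976 in 5xFAD, 0 in 5xFAD-Dp16 and 0 in the mean. In the drug interactions with Dp16, 5xFAD and 5xFAD-Dp16 and in that of 5xFAD and sex all 100 splits were as large as 0, with highest other counts of 1, 1152, 1 and 3110.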
